A study of Mus musculus with 12 samples.

How the data were processed

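White adipose tissue of mice was measured on 12 Affymetrix arrays. Per the labels, the pools came from mice fed CLA or LA, with LA as the control, and were taken at 4, 12 and 24 h. The labels call the fat pad RP and spell out neither it nor the diets; CLA and LA are the usual abbreviations of conjugated linoleic acid and linoleic acid. They do not say from when the hours were counted. Each diet and time had 2 arrays, and each array held RNA pooled from 5 mice, so 20 mice stood behind each time and 60 behind the series. Per the labels' protocols, total RNA was extracted with Trizol and 15 µg of it was made into biotinylated cRNA.

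Per the file headers and the values, the deposited table of intensity holds 1 value for each of 45101 probe sets on each array. These values are on a linear scale, with 15.7% to 18.8% of them at or below 0 on each array, the lowest being -290.3. The mean intensity ran from 91.5 to 125.1 between arrays, so the deposited intensity values had not been scaled to a common mean. No header or label names the method that summarised the probes.

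The authors also deposited 3 ratio tables, for 4, 12 and 24 h, which carry the name of the Rosetta Resolver software. Per the file headers, each table holds a ratio of group intensities, an absolute fold change, a log10 ratio with an error, and a p-value for each probe set. Their error model and the test behind the deposited p-value are not stated. The headers do not name the diet on either side of the ratio, so the direction was taken from the values. Over the 10270 probe sets with a mean of at least 500 after scaling, the ratios of each table were correlated with the CLA minus LA differences of the arrays. Pearson's r across probe sets was 0.877, 0.964 and 0.977 for the table and arrays of 4, 12 and 24 h, and at most 0.536 for a table and arrays of different times. Probe sets are not independent replicates. The ratios were therefore read as CLA over LA.

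From the deposited intensity values, each array was scaled so that its mean, after leaving out 2% of the values at each end, was 500. Scaled values under 0 were set to 0, 16 was added and log2 was taken. A fold change is therefore a ratio of scaled values plus 16. The setting of negative values to 0 was decided after the values were seen. The 64 control probe sets were left out, and a probe set was kept where at least 2 of the 12 arrays reached 100, which left 26016. Gene symbols came from the platform annotation, in which 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none. Of the gene numbers in it, 34754 were found in the reference table of gene names, and 0 symbols had changed. Each gene was represented by its probe set with the highest mean, which gave 12627 genes. No genome build came with the files, so no coordinates are given. Some genes of the lists, and Ucp2 among the genes named in advance, were not analysed here.

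The 6 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The residual degrees of freedom were 6, with 2.16 added by the prior. Contrasts compared CLA with LA at each time and averaged over the 3 times, compared these effects between times, and compared the LA pools between times. The p-values were two-sided and adjusted by Benjamini-Hochberg over the genes of each contrast, with a threshold of 0.05. Errors are standard errors of the fit unless named otherwise. Where all arrays of a group were under 100, that group was set at 100 and the fold is given as "at least". The same was done for the dim array of a group with 1 array and the mean under 100.

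For 32 gene lists, camera with a preset correlation of 0.01 was run in the 3 diet contrasts and their average. Its p-values were adjusted over the 128 tests. Beside it, camera with an estimated correlation and fry were run, and members were also counted with p-values adjusted over the list alone. Of 606 list entries, 552 were on the array. The lists cover lipogenesis, adipocyte identity, lipolysis, cholesterol synthesis, fatty acid oxidation, insulin signalling, the integrated stress response, ER chaperones and NRF2 targets. They also cover cytokines, interferon response, immediate early genes, and p53 targets together with apoptosis genes. The rest are extracellular matrix, cell cycle, circadian clock, ribosomal proteins, oxidative phosphorylation and glucocorticoid targets. Markers of macrophages, neutrophils, T and NK cells, B cells, mast cells, skeletal muscle, kidney and adrenal, liver, pancreas, endothelium, mesothelium, red blood cells, and fibroblasts with preadipocytes were lists of the same kind. All of these were chosen from general knowledge and not from these arrays.

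The gene lists, the design, the alternatives below and a rule for the genes named were fixed before the data were examined. At each time the rule takes up to 10 genes with the largest fitted change in each direction among those that passed, had both pools of one diet above both of the other, and had a mean of at least 100 in the brighter group. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not passing. Up to 4 members with the smallest p are taken from each list that passed camera at that time. Pparg, Adipoq, Lep, Il6, Ccl2, Saa3, Atf3, Trib3, Asns, Scd1 and Fasn are named at every time. Changes between times take 5 genes per direction, and the LA time course takes the circadian clock list. Genes named outside this rule are said to be so.

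The steps were tested on simulated data for CLA against LA at 24 h with the same 12627 genes. Of 50 genes each changed by 0.5, 1, 2 and 3 on the log2 scale, 0%, 18%, 62% and 82% were recovered. Of the calls at 24 h, 10 were unchanged genes, which was 10% of them, and 0 genes were called at 4 h and 0 at 12 h, where none had been changed. A list with every member shifted by 1 on the log2 scale was recovered by camera with adjusted p = 1.13e-41 and 0 other lists were called. The 10% of unchanged genes among the calls was above the threshold of 0.05. Far fewer genes were changed in the simulation than the 2716 called at 24 h in the data. The adjustment was therefore stricter there, and the shares recovered do not carry over to the data. The simulated genes varied independently of each other, so this does not test camera where genes of a list are correlated.

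The alternatives fixed in this way were quantile normalization, no scaling, offsets of 1 and 64, no filter and a filter at 200, all probe sets, the mean of a gene's probe sets, leaving out probe sets with the suffixes _x_at and _s_at, fitting only the groups compared, an intensity trend, robust empirical Bayes, blocks by replicate number, other thresholds, the authors' values, and leaving out each array in turn. An array left out leaves a single pool, which is assumed to vary like the other groups. Added after seeing the data were the Actb 3'/5' ratio of each array as a covariate, leaving out the arrays of 12 h, and no scaling with 1 factor shared by all arrays. With 2 pools per group, no array could be tested as an outlier within its group, and the number of arrays limits the precision. Files were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.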

Results

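Transcripts of white adipose tissue were measured in mice fed CLA and in control mice fed LA at 4, 12 and 24 h. Each of the 6 groups held 2 arrays, each made from RNA pooled from 5 mice, so the n of each group below is 2 pools. After scaling, 44.7% to 49.8% of the probe sets on an array reached an intensity of 100, and 12627 genes were tested. The comparisons ask which transcripts of white fat differed between the diets at each time, whether the diet effect changed between times, and which transcripts changed between times in the LA pools.

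The CLA pools of 24 h stood apart from all other arrays on the first principal component, which held 32.2% of the variance, with scores of 64.6 and 72.71. The CLA pools of 12 h had scores of -43.94 and -36.82 on the third component, which held 11% of the variance. Replicate 1 of the CLA pools of 4 h had a score of 53.09 on the second component, with 13.1% of the variance. Its signal for 18S ribosomal RNA was 27.6 after scaling, against 709 to 1442 on the other 11 arrays. The CLA pools of 4 h also had the largest difference between replicates, with an SD of 0.453 on the log2 scale over bright probe sets against 0.195 to 0.281 in the other groups. The ratio of the 3' to the 5' probe sets of Actb, a sign of RNA quality, was 3.80 to 6.41 on the arrays of 12 h and 2.35 to 4.12 on the others, and it was higher in replicate 2 in 6 of 6 groups.

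At 4 h, 7 genes were higher with CLA and 0 were lower. Chac1, a glutathione-degrading enzyme induced by ATF4, was 5.60-fold higher (log2 change 2.49 ± 0.19, adjusted p = 0.0126 by limma). Atf3, a stress-induced transcription factor, was 6.18-fold higher (2.63 ± 0.26, adjusted p = 0.0184), and the inducible chaperone Hspa1b was 6.64-fold higher (2.73 ± 0.31, adjusted p = 0.0370). Hmox1, which degrades heme, was 4.38-fold higher, the immediate early gene Ier3 6.28-fold and the matricellular protein gene Ccn1 3.30-fold. The 4 probe sets of Ccn1 ran from 0.44 to 1.91 on the log2 scale, of which 1 passed with all probe sets tested together. Pole, a DNA polymerase subunit, was at least 1.18-fold higher. In all 7 genes both pools of 1 diet were above both of the other, as in 30.5% of all genes against 33.3% by chance.

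Lists of stress and early response genes were higher with CLA at 4 h. Of 38 measured members of the integrated stress response list, the targets of ATF4, 2 rose, or 7 adjusted over the list alone, and the list was higher with adjusted p = 4.23e-08 by camera. Of its members, Trib3 had a log2 change of 2.14 (adjusted p = 0.129), Ddit3 1.52 and Ppp1r15a 1.49 (both 0.0942), none of which passed. Of 20 immediate early genes 2 rose, or 3 adjusted over the list alone, with adjusted p = 0.00136 by camera and adjusted p = 0.0532 with an estimated correlation. Jun had a log2 change of 1.07 and Btg2 of 0.84, and neither passed. Of 21 NRF2 targets 1 rose, Hmox1, and 1 adjusted over the list alone, with adjusted p = 0.00719 by camera and adjusted p = 0.0839 with an estimated correlation. Osgin1 had a log2 change of 1.28, Gstm1 0.54 and Gclm 0.42 without passing. The immediate early call ended without replicate 2 of the CLA pools of 4 h (adjusted p = 0.0554), and the NRF2 call ended without that array (0.0911) or replicate 1 of the LA pools of 4 h (0.0594).

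Other lists passed camera at 4 h with 0 members passing by limma, where 867 of all genes had an unadjusted p under 0.05 and 99 passed in the authors' deposited table. Cholesterol synthesis was lower (17 members, 0 adjusted over the list alone, adjusted p = 0.000713, adjusted p = 0.224 with an estimated correlation), with Hsd17b7 at -0.69 and Sc5d at -0.68. Cell cycle genes were lower (20 members, 0 adjusted over the list alone, adjusted p = 0.00456, adjusted p = 0.455 with an estimated correlation), with Ccnd1 at -0.98. That call ended without replicate 1 of the CLA pools (0.509) or replicate 2 of the LA pools of 4 h (0.247). Glucocorticoid targets were higher (15 members, 0 adjusted over the list alone, adjusted p = 0.00175, adjusted p = 0.302 with an estimated correlation), with Pdk4 at 0.77, but not without replicate 2 of the CLA pools (0.0910) or replicate 1 of the LA pools of 4 h (0.531). The adipocyte list was higher (26 members, 0 adjusted over the list alone, adjusted p = 0.0412, adjusted p = 0.650 with an estimated correlation). It turned lower without replicate 1 of the CLA pools of 4 h (adjusted p = 0.729) and did not pass without replicate 1 of the LA pools of 4 h (0.290), replicate 1 of the CLA pools of 12 h (0.0511), replicate 2 of the LA pools of 12 h (0.0501), either CLA pool of 24 h (0.0590) or either LA pool of 24 h (0.0535). Nor did it pass with quantile normalization (0.623) or the mean of a gene's probe sets (0.151). Lipogenesis had 0 of 26 members passing and adjusted p = 0.964.

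Transcripts of other tissues also differed at 4 h. Skeletal muscle markers were higher with CLA (10 members, 0 passing and 0 adjusted over the list alone, adjusted p = 0.00136, adjusted p = 0.356 with an estimated correlation), with a median log2 change of 1.66, or 0.36 with dim groups at the minimum. Their median level was 8.77 in replicate 2 of the CLA pools, 6.32 in replicate 1, and 5.55 and 6.04 in the LA pools, and without replicate 2 of the CLA pools the call ended (0.629). Liver markers were higher (8 members, 0 passing and 5 adjusted over the list alone, adjusted p = 1.15e-07, adjusted p = 0.143 with an estimated correlation), with a median of 1.57, or 0.62 with dim groups at the minimum. Macrophage markers were higher (22 members, 0 passing and 0 adjusted over the list alone, adjusted p = 0.0117, adjusted p = 0.557 with an estimated correlation), but not without replicate 2 of the CLA pools (0.101) or replicate 2 of the LA pools of 4 h (0.183).

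Of the genes named at every time, 1 passed at 4 h, Atf3. The log2 change was 0.17 for Pparg, the main transcription factor of fat cells, 0.24 for the fat-cell hormone Adipoq and -0.06 for Lep, which encodes leptin. It was -0.87 for the chemokine Ccl2 and 0.69 for the acute phase gene Saa3. It was 0.09 for Asns and 0.28 for Fasn, and Il6 was under 100 on all arrays of both groups. The probe set used for the desaturase gene Scd1 was at 88% to 100% of the highest value on each of the 12 arrays, so its change cannot be read at any time, and the other, at 21% to 38%, had -0.21 and did not pass. The single probe sets of Adipoq and Fasn reached 84% and 79% of that value, so their changes at each time could be larger than measured. With 0 genes lower by limma, the 5 with the smallest p among those lower, which did not pass, were Prkcz (adjusted p = 0.0524), Gata6 (0.0942), Rnf152 (0.111), Hoxc6 (0.114) and Lrrn3 (0.127). The count of 7 became 0 without replicate 2 of the LA pools of 4 h or either CLA pool of 24 h, 1 without either LA pool of 12 h, 2 without replicate 1 of the LA pools of 4 h and 31 without replicate 2 of the CLA pools of 4 h. None of the 7 calls was kept without each array in turn, and without scaling the count was 18 higher and 6 lower. With only the 2 groups of 4 h fitted it was 0.

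**Figure D1:**
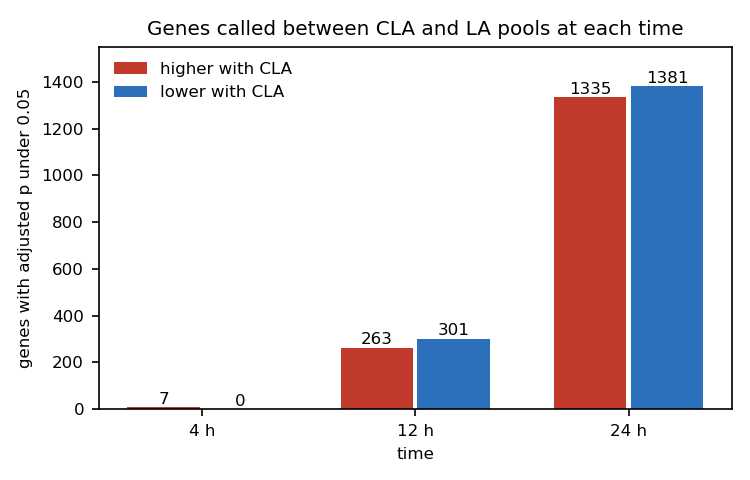
Bars give the number of genes with an adjusted p under 0.05 by limma, higher (red) or lower (blue) in the CLA than in the LA pools at each time. The counts were 7 and 0 at 4 h, 263 and 301 at 12 h, and 1335 and 1381 at 24 h.

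At 12 h, 263 genes were higher and 301 lower with CLA, and Hspa1a and Cxcl10 had the highest fitted changes. The inducible chaperone Hspa1a was 37.4-fold higher (log2 change 5.22 ± 0.60, adjusted p = 0.00541 by limma), Hspa1b 19.1-fold and the small heat shock gene Hspb1 8.92-fold. The chemokine Cxcl10 was 19.7-fold higher (4.30 ± 0.47, adjusted p = 0.00456) and the pattern-recognition protein gene Ptx3 at least 9.35-fold (adjusted p = 0.00238), with 1 of its LA arrays under 100. The pseudokinase Trib3 was 9.82-fold higher and the metallothionein Mt2 8.32-fold. The AP-1 gene Fosl1 was at least 4.74-fold higher, the amino acid transporter Slc7a5 at least 1.64-fold and the lipoprotein receptor Lrp8 at least 1.43-fold.

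Of the 10 genes with the lowest fitted changes at 12 h, 3 reached 100 on at least 1 CLA array. Ppp1r3b, which brings a phosphatase to glycogen, was 12.2-fold lower (-3.61 ± 0.28, adjusted p = 0.00153), and the related Ppp1r3c was 7.02-fold lower (-2.81 ± 0.20, adjusted p = 0.00139). The developmental gene Hoxc5 was at least 7.95-fold lower (adjusted p = 0.00824), with 1 of the 2 CLA arrays under 100. The other 7 were under 100 on both CLA arrays, so their rank depends on the offset and measured falls of other genes could be larger. Of these, Hoxc9 was at least 2.72-fold lower, Rhbdl3 at least 4.66-fold lower, the vitamin B6 phosphatase Pdxp 2.48-fold, the cell cycle factor E2f2 1.78-fold, Plekhh3 1.24-fold, the transcription factor Runx1 1.22-fold and Gm17396 1.10-fold, each as a lower bound. The 2 probe sets of Hoxc5 had -3.36 and -1.92, the 2 of Rhbdl3 -4.64 and -1.13, and the 4 of Runx1 ran from -3.15 to -0.27. In each of these genes 1 probe set passed with all probe sets tested together. In all 564 genes both pools of 1 diet were above both of the other, as in 52.7% of all genes against 33.3% by chance. Of the genes named at every time, Atf3 was 7.20-fold, Ccl2 4.39-fold and Asns, which makes asparagine, 1.76-fold higher. Those not passing were Lep at -1.18 (adjusted p = 0.0897), Pparg at -0.47 (0.102), Saa3 at 0.64, Adipoq at 0.09, the less bright probe set of Scd1 at -0.10 and Fasn at -0.01, while Il6 was under 100 on all arrays of both groups.

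Lists of lipid synthesis fell at 12 h. Of 17 genes of cholesterol synthesis and uptake 8 fell, or 14 adjusted over the list alone, with adjusted p = 1.29e-11 by camera. Among them Dhcr7, a late enzyme of cholesterol synthesis, was 6.66-fold lower, and Idi1, Sc5d and Hmgcs1 had log2 changes of -1.38, -1.34 and -1.32. Of 26 lipogenic genes 9 fell, or 11 with 1 that rose adjusted over the list alone, with adjusted p = 6.21e-08 by camera and adjusted p = 0.0746 with an estimated correlation. The lipid droplet gene Pnpla3 was 6.90-fold lower, the desaturase Scd2 2.11-fold and the elongase Elovl6 2.06-fold, and Acly, which makes acetyl-CoA for fat synthesis, also fell (adjusted p = 0.0111). In the adipocyte list 1 of 26 members fell (adjusted p = 0.0674 by camera). Of 20 cell cycle genes 3 fell, or 9 adjusted over the list alone (adjusted p = 1.58e-05 by camera, adjusted p = 0.254 with an estimated correlation), which were Ccnd1 at -1.63, Mcm2 at -1.23 and Mcm6 at -0.81.

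Lists of stress responses rose at 12 h. Of 38 genes of the integrated stress response 14 rose, or 17 with 2 that fell adjusted over the list alone (adjusted p = 4.19e-09 by camera). The transcription factor Ddit3 was 6.31-fold higher, Ppp1r15a, which restores translation, 6.03-fold and Chac1 4.50-fold. Of 21 NRF2 targets 5 rose, or 6 adjusted over the list alone (adjusted p = 7.93e-06), among them Hmox1 (6.08-fold), Srxn1, which repairs peroxiredoxins (5.58-fold), and Gclm, a subunit of the enzyme that starts glutathione synthesis (4.83-fold). Of 20 immediate early genes 5 rose, or 6 adjusted over the list alone (adjusted p = 1.58e-05), with Maff at 2.38, Ccn1 at 1.33 and Jun at 1.33. Of 29 cytokine genes 6 rose, and 6 adjusted over the list alone (adjusted p = 0.000181), with a median log2 change of 0.46, or 0.27 with dim groups at the minimum, and Cxcl2 at least 1.64-fold higher. These 4 calls held with an estimated correlation. Of 18 genes in the list of p53 targets and apoptosis 3 rose, or 4 adjusted over the list alone (adjusted p = 0.00538, adjusted p = 0.0866 with an estimated correlation). The 3 were Casp4 at 1.37, the death receptor Fas at 1.28 and the p53 regulator Mdm2 at 1.04. Of 15 glucocorticoid targets 3 rose, and 3 adjusted over the list alone (adjusted p = 0.00593, adjusted p = 0.356 with an estimated correlation), which were Mt2, Mt1 at 1.40 and the pyruvate dehydrogenase kinase Pdk4 at 1.60.

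Marker lists of other cells gave few single calls at 12 h. Of 10 skeletal muscle markers 0 passed by limma and 2 rose adjusted over the list alone (adjusted p = 0.000164, adjusted p = 0.289 with an estimated correlation), with a median log2 change of 2.63, or 1.72 with dim groups at the minimum. Their median level was 8.89 and 8.27 in the CLA pools against 5.54 and 6.57 in the LA pools. Of 22 macrophage markers 0 passed and 2 rose adjusted over the list alone (adjusted p = 0.0414, adjusted p = 0.617 with an estimated correlation), and of 21 extracellular matrix genes 0 passed and 0 adjusted over the list alone (adjusted p = 0.0394, adjusted p = 0.217 with an estimated correlation). These 2 calls ended without replicate 1 of the CLA pools (0.423 and 0.172) or replicate 2 of the LA pools of 12 h (0.318 and 0.107), and the extracellular matrix call also ended with quantile normalization (0.0536) and with the mean of a gene's probe sets (0.0607). Among all genes at 12 h, 2333 had an unadjusted p under 0.05 by limma.

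The count of 564 at 12 h depended on the other groups and on single arrays. With only the 2 groups of 12 h fitted, which leaves fewer arrays for the spread, it was 0. It was 372 without either LA pool of 4 h, 137 and 144 without replicate 1 and 2 of the CLA pools of 12 h, 102 and 56 without replicate 1 and 2 of the LA pools of 12 h, and 295 without either CLA pool of 24 h. Of the 49 calls of genes named at 12 h, 18 were kept without each array in turn, among them Hspa1a, Cxcl10, Ptx3, Trib3, Srxn1, Pnpla3 and Ppp1r3b, and 30 were lost without replicate 2 of the LA pools of 12 h. Without scaling 204 genes were higher and 459 lower, and with a single factor for all arrays 71 and 119.

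**Figure D2:**
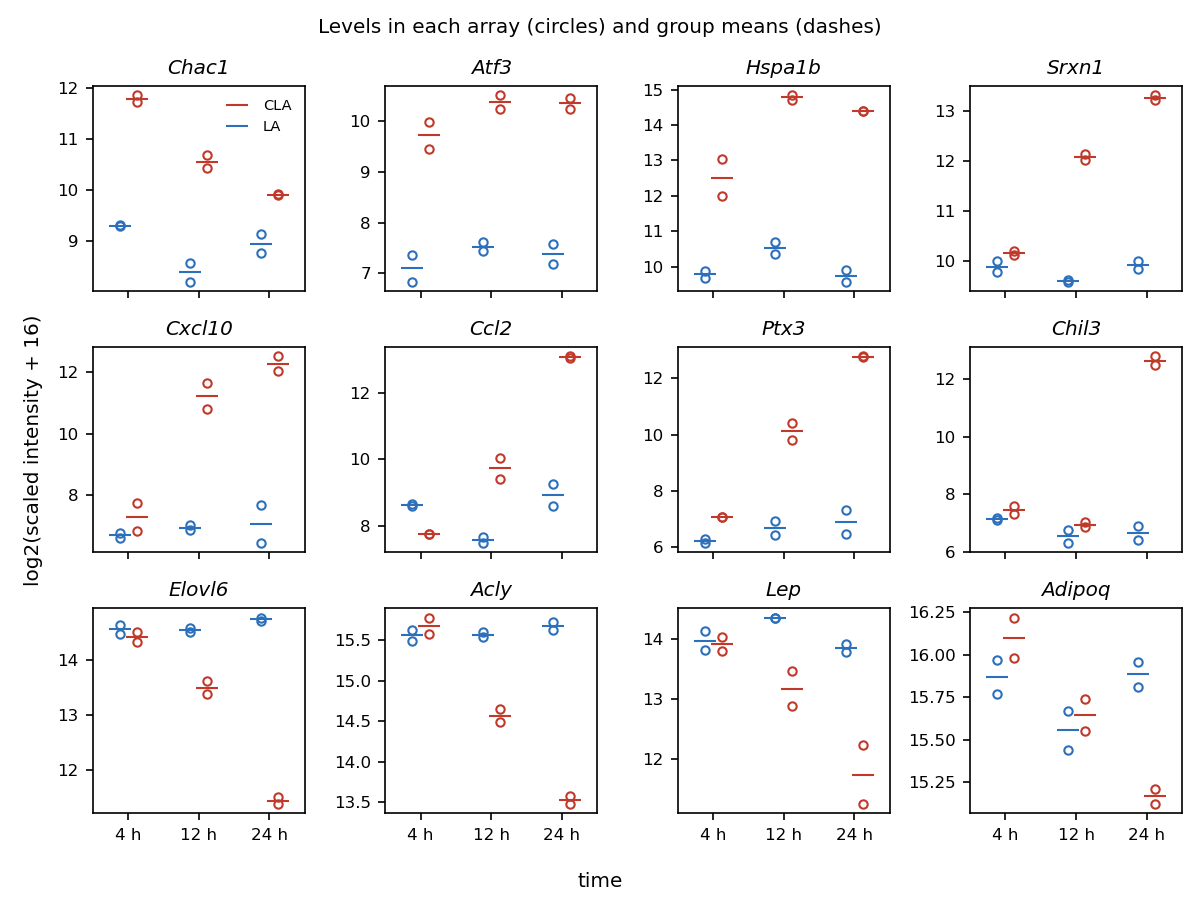
Levels of 12 genes as log2 of scaled intensity plus 16, with circles for single arrays, dashes for group means of 2 arrays, and CLA in red and LA in blue at 4, 12 and 24 h. Chac1 was 5.60-fold higher with CLA at 4 h, Cxcl10 19.7-fold at 12 h and Chil3 at least 53.6-fold at 24 h, while Elovl6 was 9.72-fold lower at 24 h.

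At 24 h, 1335 genes were higher and 1381 lower with CLA, and 3 chemokine genes were among the 10 with the highest fitted changes. Chil3, a chitinase-like protein of macrophages, was at least 53.6-fold higher (adjusted p = 2.37e-05 by limma) and Ptx3 58.5-fold (log2 change 5.87 ± 0.32, adjusted p = 8.78e-05). The neutrophil-attracting chemokines Cxcl2 and Cxcl3 were at least 23.0-fold and at least 11.7-fold higher, and Cxcl10 was 37.3-fold higher. Ccl2, which attracts monocytes, was 17.5-fold higher (4.13 ± 0.26, adjusted p = 0.000157), the cytokine Il6 at least 2.45-fold and Saa3 3.33-fold. Slfn4, a gene of myeloid cells, was at least 10.3-fold higher, Hspa1a at least 30.7-fold and Fosl1 at least 19.2-fold, while the matricellular protein gene Thbs1 was at least 21.3-fold higher and Sprr1a at least 28.4-fold. Of the LA arrays, 1 was under 100 for Chil3, Ptx3, Cxcl10, Thbs1 and Sprr1a, and with it set at 100 the fold was 50.9 for Ptx3 and 32.3 for Cxcl10. Of the stress genes named at every time, Atf3 was 7.86-fold, Trib3 4.91-fold and Asns 1.82-fold higher.

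Lep, Fasn, Pparg and Adipoq were lower with CLA at 24 h. Lep was 4.31-fold lower (-2.11 ± 0.32, adjusted p = 0.00372), the fatty acid synthase Fasn 2.72-fold (-1.44 ± 0.18, adjusted p = 0.00154) and Pparg 1.90-fold, and Adipoq fell as well (adjusted p = 0.0191). The probe sets of Adipoq and Fasn were at 64% to 78% of the highest value on the LA arrays of 24 h, so both falls could be larger than measured and no fold is given for Adipoq. The less bright of the 2 probe sets of Scd1 had -0.79 and passed with all probe sets tested together (adjusted p = 0.0190). The 10 genes with the lowest fitted changes were under 100 on both CLA arrays, so their rank depends on the offset, their folds are lower bounds, and measured falls of other genes could be larger. Ncan was at least 18.1-fold lower, Mfsd3 6.56-fold, the secreted phospholipase Pla2g2e 5.21-fold, Rilp 4.39-fold and the helicase Recql4 4.01-fold. For Pnldc1 the bound was 2.64-fold, for Hif3a, a hypoxia-inducible factor subunit, 1.96-fold, for Golga7b 1.91-fold, for Plekhh3 1.86-fold and for Gap43 1.52-fold. The 2 probe sets of Hif3a had -3.58 and -0.52, of which 1 passed with all probe sets tested together. In all 2716 genes both pools of 1 diet were above both of the other, as in 64.7% of all genes against 33.3% by chance.

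Of 26 lipogenic genes 20 fell at 24 h, or 22 adjusted over the list alone (adjusted p = 1.37e-15 by camera). Elovl6 was 9.72-fold lower (-3.28 ± 0.15, adjusted p = 3.17e-05), the acetate-activating enzyme Acss2 5.48-fold, Thrsp 5.04-fold and Acly 4.43-fold. The last 2 were at 66% to 69% of the highest value on the LA arrays, so their falls could be larger than measured. The 3 probe sets of Elovl6 ran from -3.74 to -0.46, the 3 of Thrsp from -3.67 to -0.78 and the 5 of Acly from -3.49 to -0.18. Of these, 2, 2 and 4 passed with all probe sets tested together. Of 26 genes of oxidative phosphorylation 19 fell, or 23 adjusted over the list alone (adjusted p = 7.78e-10), with a median log2 change of -0.63, Atp5o at -1.19, Uqcrfs1 at -1.15, Ndufs1 at -1.10 and Atp5g3 at -0.98. The calls of these 2 lists held with an estimated correlation. Of 26 adipocyte genes 16 fell, and 16 adjusted over the list alone (adjusted p = 1.75e-08, adjusted p = 0.212 with an estimated correlation). Klf15, a transcription factor of fat cells, was 9.88-fold lower, the lipid droplet gene Cidea 4.43-fold and the insulin-responsive glucose transporter Slc2a4 3.98-fold. Of 11 lipolysis genes 4 fell, or 5 with 1 that rose adjusted over the list alone (adjusted p = 0.0186, adjusted p = 0.311 with an estimated correlation). These were the lipases Mgll at -1.76 and Lipe at -1.46, the lactate receptor Hcar1 at -1.48 and the phosphodiesterase Pde3b at -0.88, and the last 2 restrain lipolysis. The lipolysis list did not pass with quantile normalization (0.0826).

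Sterol, oxidation and glucose genes went both ways within their lists at 24 h. Of 17 cholesterol genes 10 fell and 1 rose, the same counts adjusted over the list alone (adjusted p = 5.29e-06 by camera, adjusted p = 0.109 with an estimated correlation), with Nsdhl 4.93-fold, Lss 3.91-fold and Fdps 3.88-fold lower. The 1 that rose was Srebf2, the transcription factor of that pathway (1.44). Of 21 genes of fatty acid oxidation and thermogenesis 8 fell and 2 rose, or 10 and 2 adjusted over the list alone (adjusted p = 0.00607, adjusted p = 0.107 with an estimated correlation). Cox8b had a log2 change of -1.86, Ucp3 of -1.52 and Cox7a1 of -0.99, and the 2 that rose were Pdk4 (2.06) and the thioesterase Acot2 (1.48). Of 18 genes of insulin signalling and glucose uptake 7 fell and 2 rose, or 10 and 2 adjusted over the list alone (adjusted p = 0.0394, adjusted p = 0.212 with an estimated correlation). The glycogen synthase Gys1 was 6.31-fold lower and Pfkfb3, which drives glycolysis, 4.06-fold lower. The 2 that rose were the basal glucose transporter Slc2a1, 6.47-fold, and Trib3, which inhibits insulin signalling. The insulin list did not pass without replicate 1 of the CLA pools (0.0833) or replicate 2 of the LA pools of 24 h (0.0563), nor with quantile normalization (0.0532). Srebf2 and Acot2 were chosen after their values were seen.

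Of 29 cytokine genes 21 rose and 1 fell at 24 h, or 23 and 1 adjusted over the list alone (adjusted p = 1.29e-11 by camera), with a median log2 change of 2.17, or 1.70 with dim groups at the minimum. Besides Cxcl2 and Ptx3, the chemokine Ccl7 was 12.5-fold higher and the adhesion molecule Icam1 6.85-fold. The 1 that fell was the acute phase gene Orm1 (-1.17). Of 20 immediate early genes 13 rose and 1 fell, or 16 and 1 adjusted over the list alone (adjusted p = 4.61e-08), with Ier3 8.87-fold, Ccn1 8.17-fold and Egr1 4.63-fold higher and Nr4a2 at -1.29. The calls of these 2 lists held with an estimated correlation. Of 17 interferon response genes 8 rose, or 11 adjusted over the list alone (adjusted p = 4.07e-05, adjusted p = 0.214 with an estimated correlation), with Ifit1 at 2.03, Oasl2 at 1.74 and Cxcl9 at 1.69. Of 21 extracellular matrix genes 8 rose, or 8 with 1 that fell adjusted over the list alone (adjusted p = 0.0213, adjusted p = 0.179 with an estimated correlation). The protease Adam8 was at least 6.80-fold higher, the protease inhibitor Timp1 8.45-fold and the collagen cross-linking enzyme Lox 2.84-fold. Orm1 and Nr4a2 were chosen after their values were seen.

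Stress lists rose at 24 h as well. Of 21 NRF2 targets 8 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 0.000113 by camera), with Srxn1 10.2-fold higher (3.35 ± 0.14, adjusted p = 2.37e-05), Hmox1 7.24-fold, the thioredoxin reductase Txnrd1 4.55-fold and Gclm 3.83-fold, and Gsta4 at -0.98. The 3 probe sets of Txnrd1 ran from 0.16 to 2.18, of which 1 passed with all probe sets tested together. Of 20 ER chaperone genes 9 rose, or 10 adjusted over the list alone (adjusted p = 1.16e-05), with Creld2 higher (adjusted p = 0.00124), Manf at 1.81, Hspa5 at 1.45 and Hsp90b1 at 1.34. The calls of these 2 lists held with an estimated correlation. Of 38 genes of the integrated stress response 17 rose and 5 fell, or 19 and 6 adjusted over the list alone (adjusted p = 0.00265, adjusted p = 0.0646 with an estimated correlation), with Ppp1r15a at 2.19 and the amino acid transporter subunit Slc3a2 at 1.66. The 5 that fell were the lipoprotein receptor Vldlr (-1.95), the serine synthesis genes Psph (-1.11) and Phgdh (-0.78), the cysteine-making enzyme Cth (-0.86) and the transaminase Gpt2 (-1.28). Of 18 genes in the list of p53 targets and apoptosis 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.0107, adjusted p = 0.107 with an estimated correlation). Among them Gadd45b was 7.23-fold and Casp4 5.23-fold higher, and Phlda3 was at -1.66. The p53 list did not pass without replicate 2 of the LA pools of 24 h (0.0563). Gsta4, Psph, Phgdh, Cth, Gpt2 and Phlda3 were chosen after their values were seen.

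Of 20 cell cycle genes 4 fell at 24 h, and 0 adjusted over the list alone (adjusted p = 0.0213 by camera, adjusted p = 0.558 with an estimated correlation). These were the mitotic genes Cdk1 at -1.07, Top2a at -1.07 and Mki67 at -0.83, and Birc5, at least 1.44-fold lower. With all probe sets tested together only Cdk1 of these passed, and the other of the 2 probe sets of Top2a had 0.10. The list did not pass without replicate 1 of the CLA pools (0.0526) or replicate 1 of the LA pools of 24 h (0.281). Of 15 glucocorticoid targets 5 rose and 2 fell, or 6 and 2 adjusted over the list alone (adjusted p = 0.0468, adjusted p = 0.529 with an estimated correlation), and the 2 that fell were Tsc22d3 (-1.04), chosen after its value was seen, and Hif3a. That list did not pass without either CLA pool of 4 h (0.0538), replicate 1 of the CLA pools of 12 h (0.0512), replicate 1 or 2 of the LA pools of 12 h (0.0590 and 0.0611), replicate 2 of the CLA pools of 24 h (0.0895) or replicate 1 of the LA pools of 24 h (0.0857).

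Markers of myeloid cells were higher with CLA at 24 h. Of 22 macrophage markers 14 rose, and 14 adjusted over the list alone (adjusted p = 8.86e-06 by camera, adjusted p = 0.269 with an estimated correlation). The Fc receptor Fcgr1 was 8.92-fold higher, the scavenger receptor Msr1 8.30-fold, the pore-forming Mpeg1 4.19-fold and the adaptor Tyrobp 2.76-fold. Adgre1 (0.10), Csf1r (0.11) and Cd163 (-0.10), chosen after their values were seen, did not pass, and without scaling Cd163 was above 0. Of 7 neutrophil markers 4 rose, or 5 with 1 that fell adjusted over the list alone (adjusted p = 0.0166, adjusted p = 0.128 with an estimated correlation). The median log2 change of the neutrophil list was 1.69, or 0.40 with dim groups at the minimum. S100a9 was at least 9.39-fold higher, the receptor Csf3r at least 1.30-fold, the protease Mmp9 3.62-fold and S100a8 3.23-fold. Ngp and Mpo, which are abundant in neutrophil granules, did not pass (adjusted p = 0.660 and 0.112), and were chosen after their values were seen. Of the macrophage markers 19 of 22, and of the neutrophil markers 1 of 7, reached 100 on all 6 LA arrays, and 0 were in another list. Of 8 liver markers 3 fell, or 5 adjusted over the list alone (adjusted p = 0.00501, adjusted p = 0.442 with an estimated correlation), with Alb 3.04-fold lower and Fgb at least 1.70-fold lower. Their median log2 change was -1.75, or -1.14 with dim groups at the minimum. Their median level was 9.64 and 9.19 in the LA pools against 7.42 and 8.22 in the CLA pools. The LA pools of 4 h had 6.25 and 6.94 and those of 12 h 7.21 and 7.73. The liver signal was thus higher in the LA pools of 24 h than on any other array.

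**Figure D3:**
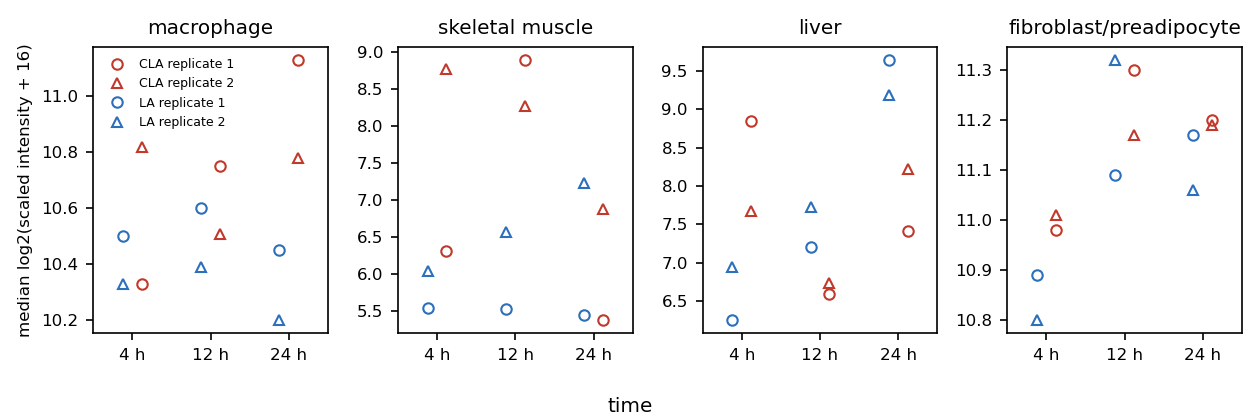
Median level of the marker genes of macrophages, skeletal muscle, liver, and fibroblasts with preadipocytes on each array, as log2 of scaled intensity plus 16, with circles for replicate 1, triangles for replicate 2, and CLA in red and LA in blue. At 4 h the muscle markers were at 8.77 in replicate 2 and 6.32 in replicate 1 of the CLA pools.

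The remaining lists did not pass camera at 24 h. Of 16 circadian clock genes 5 fell (adjusted p = 0.746), and of 17 ribosomal protein genes 0 passed (0.909). Of 8 markers of T and NK cells 2 rose and 1 fell (0.746), which were Ccl5 and Il7r and the T cell marker Thy1, and of 5 B cell markers 1 fell (0.552). Of 5 mast cell markers 0 passed (0.964), of 10 skeletal muscle markers 0 (0.900), of 9 mesothelial markers 0 (0.456) and of 4 red blood cell markers 0 (0.475). Of 5 kidney and adrenal markers 1 rose, Star, which carries cholesterol into mitochondria (0.303), and the single pancreas marker measured, Cela1, fell (-1.08, list adjusted p = 0.174). Of 11 endothelial markers 1 rose and 1 fell (0.522), and of 11 markers of fibroblasts and preadipocytes 1 rose and 1 fell (0.639). The genes named in this paragraph were chosen after their values were seen. The medians of the lists of clock, B cell, mast cell and fibroblast genes changed sign under at least 1 other scaling.

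The count of 2716 at 24 h was 1315 with only the 2 groups of 24 h fitted. It was 1396 and 1101 without replicate 1 and 2 of the CLA pools of 24 h, and 1639 and 1484 without replicate 1 and 2 of the LA pools of 24 h. Of the 98 calls of genes named at 24 h, 81 were kept without each array in turn. The other 17, among them Adipoq, Saa3, Asns, Alb, Lipe, S100a8, Mmp9 and Mki67, were lost without at least 1 array, with 14 lost without replicate 2 of the CLA pools of 24 h. Without scaling, 1970 genes were higher and 737 lower, and with a single factor for all arrays 1264 and 508. Without scaling the median change of all genes was 0.16 at 24 h against 0.02 with it, -0.10 against 0.02 at 4 h and -0.12 against -0.02 at 12 h.

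**Figure D4:**
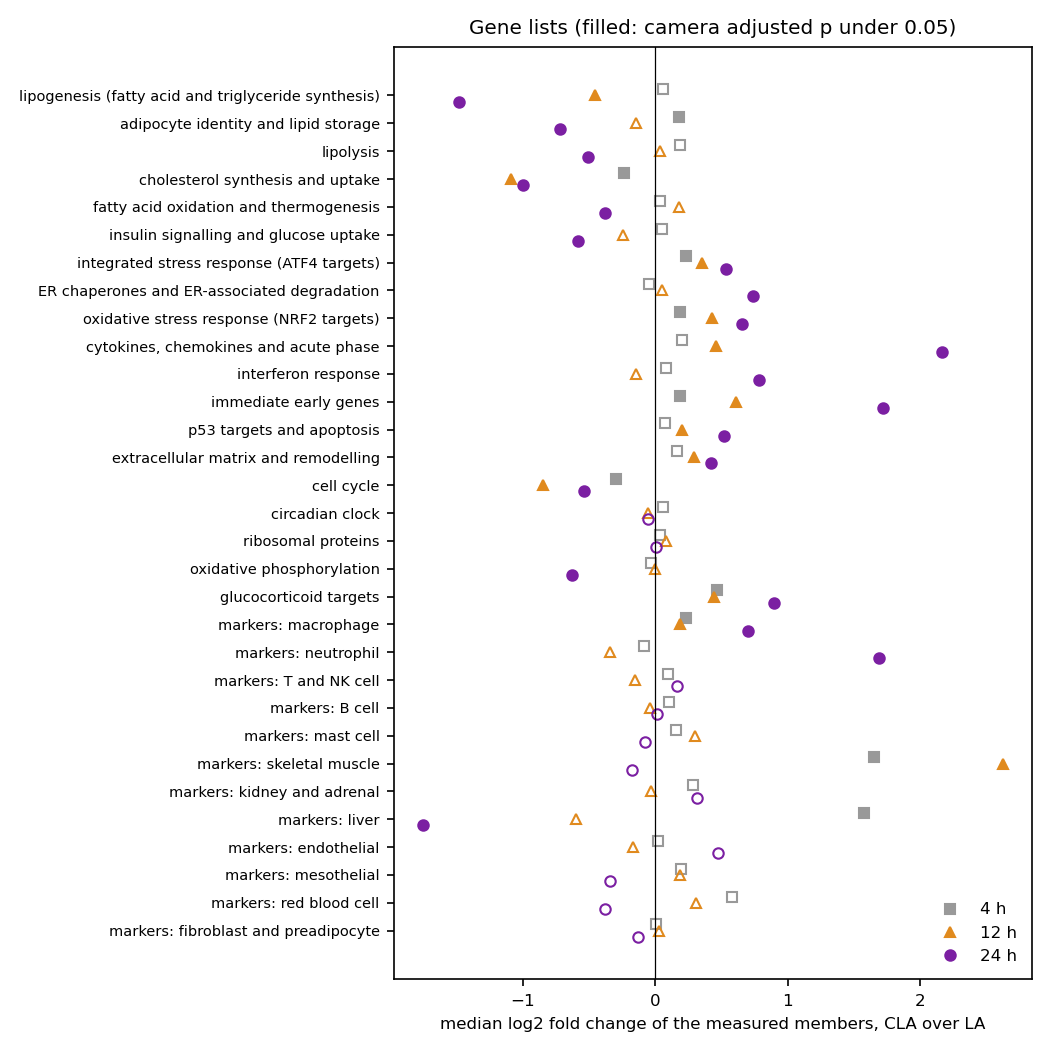
Median log2 change, CLA over LA, of the measured members of 31 gene lists at 4 h (grey squares), 12 h (orange triangles) and 24 h (purple circles), filled where camera gave an adjusted p under 0.05. At 24 h the cytokine list had a median of 2.17 and the oxidative phosphorylation list of -0.63, and some medians near 0 of lists that did not pass changed sign under other scalings.

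Averaged over the 3 times, 931 genes were higher and 977 lower with CLA. Lists of lipid synthesis fell, with 19 of 26 lipogenic genes (21 with 1 that rose adjusted over the list alone, adjusted p = 1.78e-13 by camera) and 13 of 17 cholesterol genes (14 adjusted over the list alone, adjusted p = 3.06e-10). Lists of stress and inflammation rose, with 16 of 29 cytokine genes (21 adjusted over the list alone, adjusted p = 3.21e-11), 11 of 20 immediate early genes (13 adjusted over the list alone, adjusted p = 5.73e-09) and 8 of 21 NRF2 targets with 1 that fell (10 and 1 adjusted over the list alone, adjusted p = 5.29e-06). In the integrated stress response 17 of 38 genes rose and 3 fell (21 and 5 adjusted over the list alone, adjusted p = 6.16e-07). These 6 calls held with an estimated correlation, and in all 18 of the 58 list calls of the 3 times and their average did. The adipocyte list had 6 of 26 members lower (13 adjusted over the list alone, adjusted p = 7.95e-05, adjusted p = 0.356 with an estimated correlation) and oxidative phosphorylation 5 of 26 (9 adjusted over the list alone, adjusted p = 8.21e-06, adjusted p = 0.0597 with an estimated correlation). The gene count of 1908 was 1249 without replicate 1 of the LA pools of 4 h and 1179 without replicate 2 of the CLA pools of 24 h. Median, mean and test had the same sign in the 58 list calls and differed in 17 list tests that did not pass.

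Genes that differed at more than 1 time went mostly in the same direction. Of the 7 genes higher at 4 h, 5 were also higher at 12 h, against 0.15 for independent lists (Fisher's exact test, two-sided p = 7.66e-08), and 6 at 24 h against 0.74 (p = 8.81e-06 by the exact test), where 1 was lower. At both 12 and 24 h 198 genes were higher, against 27.8 for independent lists, and 173 were lower, against 32.9, while 2 that were higher and 7 that were lower at 12 h had the opposite call at 24 h. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.206 between 4 and 12 h, 0.338 between 12 and 24 h and 0.061 between 4 and 24 h. The times share no arrays, though they share the estimate of the spread.

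The diet effect itself changed between times, most often between 4 and 24 h. From 4 to 24 h it became more positive in 420 genes and more negative in 440. Srxn1 (log2 difference 3.07 ± 0.20, adjusted p = 0.000598) and Cbr3, a carbonyl reductase (3.47 ± 0.20, adjusted p = 0.000406), became more positive, as did Chil3 and the nuclear RNA Malat1 (4.23 ± 0.25). Elovl6 (-3.15 ± 0.21, adjusted p = 0.000598), Acss2 (-2.49) and Acly (-2.27) became more negative. From 12 to 24 h the effect became more positive in 161 genes, among them Chil3, the phosphatase Dusp5, Malat1 (3.39) and Icam1 (3.18). It became more negative in 125, among them Elovl6 (-2.24), the transaminase Gpt (-2.23), Pxmp2 (-2.06) and Thrsp (-2.05). From 4 to 12 h 3 genes changed, Cbr3 (2.37 ± 0.20, adjusted p = 0.0212), Srxn1 (2.21 ± 0.20, adjusted p = 0.0233) and Pole (adjusted p = 0.0400). Slfn4, Hif3a and Pole also changed from 4 to 24 h, and Slfn4 and Hif3a from 12 to 24 h, but some groups of these 3 genes, of Chil3 and of Dusp5 were under 100 on all arrays, so their values depend on the offset.

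These counts of changes between times rested on few arrays. From 4 to 24 h, the count of 860 was 280 and 245 without replicate 1 and 2 of the LA pools of 4 h, 1793 without replicate 2 of the CLA pools of 4 h, 552 without either CLA pool and 539 without either LA pool of 12 h, 299 and 183 without replicate 1 and 2 of the CLA pools of 24 h, and 453 and 311 without those of the LA pools of 24 h. All 10 named genes kept their calls without each array. From 12 to 24 h, the count of 286 was 620 without either CLA pool and 112 without either LA pool of 4 h, 27 and 107 without replicate 1 and 2 of the CLA pools and 32 and 28 without those of the LA pools of 12 h, and 50 and 35 without those of the CLA pools and 138 and 45 without those of the LA pools of 24 h. Of the 10 named genes 7 kept their calls, and Gpt, Pxmp2 and Thrsp lost theirs without replicate 1 of the CLA pools of 12 h. From 4 to 12 h, the count of 3 was 0 without replicate 1 of the CLA pools or either LA pool of 4 h, replicate 2 of the CLA pools or either LA pool of 12 h, or either CLA pool of 24 h, and it was 1 without replicate 1 of the CLA pools of 12 h, 6 without either LA pool of 24 h and 7 without replicate 2 of the CLA pools of 4 h. By limma 1244 genes had an unadjusted p under 0.05 there. Without scaling, the count was 868 more positive and 92 more negative from 12 to 24 h, 1103 and 242 from 4 to 24 h, and 23 and 16 from 4 to 12 h. Unscaled values are smaller, so the offset weighs more there, and with a single factor for all arrays the counts were 94 and 6, 296 and 70, and 1 and 2.

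In the LA pools few genes passed between times, which with 2 pools per group does not show that few changed. From 4 to 12 h Tmem216, a cilium gene, fell (-2.24 ± 0.20, adjusted p = 0.0387 by limma), with group means of 10.67 at 4 h, 8.43 at 12 h and 9.57 at 24 h. From 12 to 24 h Scarf1 rose and Pgr fell (both adjusted p = 0.0434), with 4 and 5 of the 6 LA arrays under 100, so no fold is given. From 4 to 24 h 0 genes passed by limma, with 1032 at an unadjusted p under 0.05, against 2166 from 4 to 12 h and 1287 from 12 to 24 h. These 3 genes were chosen after their values were seen. None of the clock genes passed, and the values nearest to passing were those of the clock repressors Cry1 (2.04 ± 0.48, adjusted p = 0.163) and Nr1d1 (at least 3.53-fold lower, adjusted p = 0.163) from 4 to 12 h. From 12 to 24 h the period gene Per2 was at least 3.17-fold lower (adjusted p = 0.300), and from 4 to 24 h Nfil3 had a change of -1.68 ± 0.24 (adjusted p = 0.179). Without single arrays the 3 counts ran from 0 to 4, 0 to 3 and 0 to 2. Without scaling, where the median change of all genes from 12 to 24 h reached -0.28, they were 87 genes higher and 24 lower from 4 to 12 h, 16 and 144 from 12 to 24 h, and 12 and 23 from 4 to 24 h. Unscaled values are smaller, so the offset weighs more there, and with a single factor for all arrays the counts were 2 and 1, 0 and 1, and 0 and 0.

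The authors' deposited tables of ratios gave the same direction for nearly all called genes. The direction of the ratios had itself been taken from their correlation with these arrays, so the shared sign is not an independent check. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table of each time over the same genes, 45 were higher and 54 lower at 4 h, 882 and 930 at 12 h, and 1994 and 1982 at 24 h. All 7 genes called by limma at 4 h, 563 of 564 at 12 h and 2711 of 2716 at 24 h had the same sign in the authors' deposited table of that time, and 6, 503 and 2337 of them also passed there. Across genes, Pearson's r between the ratios of the authors' deposited table and the log2 changes was 0.781 at 4 h, 0.868 at 12 h and 0.915 at 24 h.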

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

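The tests of the change of the diet effect between times were planned, while the tests of cell makeup, RNA quality and muscle RNA and the count over other splits were chosen after the results were seen.

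Between times, the effect of CLA against LA changed in 3 genes from 4 to 12 h, in 286 from 12 to 24 h and in 860 from 4 to 24 h, by the test of the difference itself. From 4 to 12 h the log2 differences were 2.371 in Cbr3, 2.207 in Srxn1 and -3.823 in Pole. From 12 to 24 h they were 6.222 in Slfn4, 5.554 in Chil3, 4.038 in Dusp5, 3.387 in Malat1 and 3.176 in Icam1. In the other direction they were -3.752 in Hif3a, -2.237 in Elovl6, -2.225 in Gpt, -2.057 in Pxmp2 and -2.051 in Thrsp. From 4 to 24 h they were 6.222 in Slfn4, 5.645 in Chil3, 4.234 in Malat1, 3.469 in Cbr3 and 3.074 in Srxn1. In the other direction they were -5.093 in Pole, -4.387 in Hif3a, -3.148 in Elovl6, -2.492 in Acss2 and -2.266 in Acly. The fitted values of Slfn4, Chil3, Dusp5, Hif3a and Pole rest in part on groups under 100 on all arrays and depend on the offset.

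Probe sets without a single gene name stand outside the comparisons of genes. Of 3959 that were bright enough, 15 were higher and 27 lower with CLA at 12 h, and 180 were higher and 176 lower at 24 h.

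The averaged diet effect was set against other splits of the arrays within times. Of 100 splits drawn from 108, 1 gave as many genes as the real split with 1908, namely the real one, so a chance split can be excluded at that share. The highest of the others gave 1703 and parts 2 of the 3 times by diet, and the median of the others was 0.

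The lower lipogenic and adipocyte transcripts at 24 h may come from fat cells that changed or from a lower share of fat cells in the CLA pools. A lower share alone would raise the markers of all other cells alike, but macrophage markers changed by 1.019 more on average than markers of endothelial, fibroblast and mesothelial cells (permutation p = 1e-05, the smallest the permutations can give, two-sided, 22 and 31 genes). Genes of a list are not independent, as that p takes them to be, but between arrays the difference was 1.019 ± 0.221, though the macrophage list itself had adjusted p = 0.269 with an estimated correlation. A rise within macrophages would give such a gap at any share of fat cells, so the gap does not measure that share. The other markers had a mean change of -0.06. Their medians were 0.469 for endothelial, -0.345 for mesothelial and -0.130 for fibroblast markers. RNA quality differed between arrays, and with the Actb 3'/5' ratio as covariate 22 of 26 lipogenic genes were lower, against 20 without it. At 24 h that ratio was 3.25 to 4.12 in the CLA pools and 2.64 to 4.07 in the LA pools. These ranges overlap, so the covariate could take up little of a diet difference, and other measures of RNA quality were not tried as covariates. Other cells entering while fat cells were lost stays open, since pooled tissue does not part the 2, and that diet changed transcripts within fat cells is a hypothesis found and tested on the same arrays.

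The higher cytokine transcripts at 24 h may come from resident cells or from immune cells that entered the tissue. More macrophages of unchanged makeup would raise their markers about as much as the cytokines, and the median change of the macrophage markers was below that of the cytokine list by a difference of -1.469 (permutation p = 0.0025, two-sided, 22 and 29 genes, taken as independent). With arrays under 100 set at 100 the difference was -0.997 (permutation p = 0.0081, two-sided), short of the 1 asked for. Between arrays, without setting any at 100, the mean difference was -1.414 ± 0.135. Since the difference depends on the dim arrays, this test cannot decide whether more macrophages of unchanged makeup were the only source of the cytokine rise. More macrophages of changed makeup stay open. Neutrophils stay open too, since 4 of 7 neutrophil markers were called higher, with S100a9 at least 9.39-fold and S100a8 3.23-fold higher, while Ngp and Mpo did not pass (adjusted p = 0.660 and 0.112), and macrophages can express some of these markers too. Activation of cells already present was not tested apart from these, and the diet itself stays among the open explanations.

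The higher skeletal muscle transcripts at 4 and 12 h may come from muscle carried into single pools. At 4 h the markers differed between the CLA replicates by a median of 3.269, with 9 of 10 higher in replicate 2 and 1 of 10 at 100 or more on all LA arrays, which fits muscle RNA in that pool. At 12 h the CLA replicates differed by -0.546 and both were above the LA pools, so carried muscle cannot be told apart from diet there, because each diet has 2 pools. The LA replicates differed by 1.099 at 12 h and 2.31 at 24 h, so muscle signal also varied between pools of the same diet.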

How the results depend on the processing

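Of the tests here, those with the Actb 3'/5' covariate, without the arrays of 12 h and with a single factor for all arrays were chosen after the results were seen. The counts below are of genes called in CLA against LA at 4 h, 12 h, 24 h and averaged (7, 564, 2716 and 1908), in the change of the CLA effect from 4 to 12 h, 12 to 24 h and 4 to 24 h (3, 286 and 860), and in the LA pools at 12 against 4 h, 24 against 12 h and 24 against 4 h (1, 2 and 0). Counts not given stayed within 1.5 times these. Named genes had 8535 values under alternatives, of which 7896 kept direction and side of the threshold, 561 no longer passed, 76 newly passed and 2 reversed.

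Without scaling between arrays, the count at 4 h was 24, the changes were 39, 960 and 1345, and the LA pools gave 111, 160 and 35. With a single factor for all arrays, the diet counts were 2, 190, 1772 and 1018, the changes from 12 and from 4 to 24 h 100 and 366, and the LA pools at 12 against 4 h and 24 against 12 h 3 and 1. With quantile normalization the LA pools gave 1 at 24 against 12 h, and of the calls at 4, 12 and 24 h it kept 7, 521 and 2575.

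With an offset of 1, the count at 4 h was 11 and the LA pools gave 2, 0 and 2. With an offset of 64, the changes from 4 to 12 h and 12 to 24 h were 10 and 473, and the LA pools at 12 against 4 h and 24 against 12 h gave 2 and 0. Hif3a reversed from 12 to 24 h with an offset of 1, to 0.203 (adjusted p = 0.884), where its dim groups weigh most by construction. Without a filter the LA pools gave 3, 6 and 2. With a filter at 200, the changes were 15, 706 and 1339, and the LA pools at 12 against 4 h and 24 against 12 h gave 3 and 0.

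Over all probe sets, the count at 4 h was 11, the changes from 4 to 12 h and 12 to 24 h were 0 and 127, and the LA pools at 12 against 4 h and 24 against 12 h gave 0 and 0. With the mean of a gene's probe sets, the change from 12 to 24 h was 169 and the LA pools gave 0 at 12 against 4 h. Without probe sets with the suffixes _x_at and _s_at, the change from 4 to 12 h was 1 and the LA pools gave 0 at 12 against 4 h, and Gpt reversed from 12 to 24 h, to 0.849 (adjusted p = 0.738), because another probe set then stands for it.

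Fitting only the groups compared, with fewer arrays for the spread, gave 0, 0 and 1315 at 4, 12 and 24 h, changes of 0 from 4 to 12 h and 250 from 4 to 24 h, and 0 and 0 in the LA pools at 12 against 4 h and 24 against 12 h. With an intensity trend the counts were 23 at 4 h and 928 at 12 h, the changes were 83, 982 and 1645, and the LA pools gave 139, 9 and 13. At an adjusted p under 0.10 the counts were 15 and 951 at 4 and 12 h, the changes were 14, 929 and 1786, and the LA pools at 12 against 4 h gave 2. With a minimum of 1.5-fold, the averaged count was 1058. Without the arrays of 12 h the count at 4 h was 0 and the change from 4 to 24 h 250, while 1898 genes were called at 24 h. With the Actb covariate the change from 4 to 12 h was 0 and the LA pools at 12 against 4 h and 24 against 12 h gave 0 and 0. The p-values of the authors' deposited table gave 99 at 4 h and 1812 at 12 h.

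The replicate numbers were not taken to pair the samples, since no label says that they mark a shared batch. The deviations of CLA and LA pools with the same number correlated by 0.092, 0.080 and 0.061 at 4, 12 and 24 h, which does not exclude a shared technical difference such as that of the Actb ratio. With the replicate number as a replicate block, the diet counts were 9, 499, 2775 and 1955, the change from 4 to 12 h was 0, and the LA pools at 12 against 4 h and 24 against 12 h gave 0 and 1. With a replicate block of number within time, which leaves fewer degrees of freedom, the diet counts were 0, 52, 2170 and 1338, the changes were 0, 8 and 173, and the LA pools at 12 against 4 h and 24 against 12 h gave 0 and 0.

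Without single arrays, which leaves a lone pool assumed to vary like the other groups, the diet counts ran from 0 to 31 at 4 h, 56 to 788 at 12 h, 1101 to 3306 at 24 h and 1179 to 2247 averaged. The changes ran from 0 to 7, 27 to 620 and 183 to 1793, and the LA pools from 0 to 4, 0 to 3 and 0 to 2. Of the 58 list calls by camera, 18 remained with an estimated correlation, 54 with quantile normalization and 46 with fry. Without single arrays some list calls were lost, as given with each list above. The adipocyte list at 4 h reversed without replicate 1 of the CLA pools of 4 h (adjusted p = 0.729, the highest without single arrays, where the lowest was 0.000516), the only reversal among 2176 list values. Where no cause is given, the cause was not tested. Signal over background limits the genes under 100, whose folds are bounds.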

Other observations

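The genes here and the tests of them were chosen after the results were seen. Besides Hspa1a, Hspa1b and Hspb1, the co-chaperones Dnajb1 (log2 change 1.40 at 12 h and 2.74 at 24 h), Hsph1 (1.70 and 2.09), Dnajb4 (1.51 and 1.63) and Bag3 (1.56 and 1.33) passed as higher at both times by limma. So did the chaperones Hsp90aa1 (1.23 and 1.49) and mitochondrial Hspd1 (0.73 and 0.82), while Hspa8 (0.82, adjusted p = 0.00844) and Hspe1 (1.31, adjusted p = 0.00548) passed at 24 h and did not pass at 12 h (0.311 and 0.0556). At 4 h 1 of these 11 genes passed, Hspa1b. These directions were the same under quantile normalization and without scaling. The change of the effect from 12 to 24 h did not pass for Hspa8 (0.49, adjusted p = 0.251) or Hspe1 (0.36, adjusted p = 0.555).

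Of 6 genes that act on glycogen, 5 were lower with CLA at 24 h. Ppp1r3b had a log2 change of -2.81 and Ppp1r3c of -1.89, the glycogen synthase Gys1 of -2.66, the phosphorylase Pygl of -1.74 and the branching enzyme Gbe1 of -0.98, and these 5 passed. Ugp2, which makes the precursor, had 0.51 and did not pass (adjusted p = 0.0845).

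Of the HoxC cluster, averaged over the 3 times, Hoxc5 (-2.27), Hoxc6 (-1.16), Hoxc8 (-0.83) and Hoxc10 (-0.75) passed as lower with CLA, and Hoxc4 (0.08) and Hoxc9 (adjusted p = 0.650) did not. Hoxc9 was at least 2.72-fold lower at 12 h and under 100 on all arrays of 4 and 24 h. Of other Hox genes, Hoxa9 passed (-0.77, adjusted p = 0.0369), and Hoxa5, Hoxa10, Hoxd8 and Hoxd9 did not.

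The nuclear RNA Malat1 was higher with CLA at 24 h, by 4.25 on the log2 scale in the probe set used, and its 7 probe sets ran from 0.14 to 4.25, of which 4 passed. Neat1, another nuclear RNA, had -0.05 and did not pass, and was above 0 under quantile normalization and without scaling. Star, a cholesterol carrier of steroid-making cells, was 9.34-fold higher at 24 h (3.22 ± 0.20, adjusted p = 0.000157). The probe sets used for the fat-cell genes Fabp4 and Lpl were at 95% to 100% and 77% to 88% of the highest value on each array, so their changes cannot be read. Of their less bright probe sets, the 1 of Lpl had -0.86 at 24 h and passed with all probe sets tested together (adjusted p = 0.0175), and the 3 of Fabp4 did not pass. Cd36, at 42% to 54%, had -0.25 and did not pass.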
